A study of Homo sapiens with 8 samples.

How the data were processed

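Small RNA sequencing libraries were made from HK2 cells, an immortalised line of human renal proximal tubule epithelium. Per the labels' protocols, the cells were serum starved for 24 h and then left untreated or exposed to TGF-beta1, a cytokine that drives fibrosis. The dose was 20 ng/mL and the exposure lasted 24 h in some libraries and 48 h in others. All cells, controls included, received the nucleoside analogue 4-thiouridine at 100 µM for the last 20 h before harvest. Small RNA was cut from a gel before the library preparation, and the reverse-transcribed product was cut from a second gel. There were 8 libraries: 4 controls, numbered 1 to 4 in their titles, 2 libraries at 24 h, numbered 1 and 2, and 2 libraries at 48 h, numbered 3 and 4. Groups and numbers were taken from the labels. Nothing in the labels says whether the libraries of a group came from separate cultures, nor at which time the controls were harvested, so p-values measure only the spread between these libraries, which may be technical.

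The authors deposited 1 table of miRNA reads as CPM (counts scaled to a common library total), rounded to 1 decimal, for 1615 mature miRNAs of miRBase 21, per the file headers. A further text column holds the most frequent sequence read for each miRNA in control library 1, per the file headers. Reads were converted with bcl2fastq 2.20.0.422, per the submitters' processing notes. The aligner and the genome build are not given in the sources used here. The CPM of 1 library sum to between 68.9% and 86.4% of its reads, so the denominator also holds reads not listed as miRNAs. All value columns were mapped to a sample.

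The depth was estimated from the low values. In each library, the step that best fitted the values of at most 20 CPM was taken as the worth of 1 read. It gave between 1440922 and 3091190 reads per library. Between 91.3% and 95.9% of these low values were whole multiples of the step within 0.05 CPM, against 14.4% to 31.0% by chance. The others were fractions of a read, as a split of reads between entries gives, so whole reads were not taken as recovered, and the tests for counts that had been planned for recovered reads were not run. At these depths 10 CPM is between 14.4 and 30.9 reads, and 3 reads are between 0.971 and 2.08 CPM. These figures cover counting error only, since the reads carry no molecular identifiers.

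The tests were run in R 4.3.3 with limma 3.58.1 on log2(CPM + 1), on the 296 miRNAs with a mean of at least 10 CPM over the 8 libraries. Another 285 entries were at 0 in all 8 libraries. Linear models with a mean-variance trend were fitted, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low miRNAs. All treated libraries were compared with all controls in a 2-group fit, which is the comparison the series states. The exposure times were compared with control and with each other in a 3-group fit over all 8 libraries. There were 22 miRNA lists (clusters, seed families, markers of other cell types, and entries that overlap other small RNAs). The 16 with at least 3 tested members were tested with camera, which compares a list with the other tested miRNAs, at a preset correlation of 0.01, with adjustment over the lists of 1 comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, p-values rose even where the estimate lay below the preset 0.01. For the TGF-beta and fibrosis list at 48 h it was -0.07, and the unadjusted camera p went from 0.00226 to 0.0237. With the replicate block too, the smallest adjusted p of any list in any comparison was 0.448. A call lost with this setting therefore does not by itself show correlated members. For the 14q32 list, however, the estimate was 0.395 in treated against control and 0.0881 in the fit of exposure times. Both lie above the preset, so correlation between its members may make its preset p too small. Comparisons, lists and the rule for naming miRNAs were fixed before the data were examined. The rule named the tested members of the miR-17~92 cluster and of its seed family, the 5 smallest p-values in each direction for treated against control, the 3 smallest for each of the other comparisons, the 10 most abundant miRNAs and the 2 most abundant members of each list. It gave 64 miRNAs. The calls of the fits with a replicate block and the remaining members of the 14q32 list were named after their values were seen, which makes 78.

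Controls and treated libraries share title numbers, so each fit was repeated with the number as a block. The deviations of same-numbered control and treated libraries from their group means correlated at 0.62 to 0.72 in all 4 pairs, which meets the rule set for taking the numbers as pairs. The pairing comes from the numbers in the titles. Libraries with different numbers within the pair of 1 and 2, or of 3 and 4, correlated at 0.42 to 0.74, and libraries across these sets at -0.74 to -0.54, so most of the shared deviation lies between the 2 sets of numbers. The rule therefore cannot tell pairs by number from these 2 sets. A block with only these 2 levels was added after seeing the data. In the 3-group fit the replicate block leaves 2 residual degrees of freedom, and the estimate of the spread then comes from all tested miRNAs. The SE and p-values of that fit therefore do not measure how well the pairs of a given miRNA agree.

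CPM are shares of a total. The median of all tested log2 fold changes was -0.23 for treated against control, -0.41 at 24 h and 0.07 at 48 h. With median-of-ratios scaling these medians were -0.08, -0.04 and 0.01. List changes are therefore also given relative to the median of all tested miRNAs. Other alternatives were the pseudocount, the filter on low values, quantile normalization, CPM recomputed without the 10 most abundant miRNAs, limma without the trend, matched controls only, and leaving out each library.

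The fits were tested on simulated data for 296 miRNAs, with the real means and the real difference between the number sets, and with 60 miRNAs changed in each of 50 draws. Noise was drawn independently for each miRNA, at the spread left after group and title number were fitted. The simulation thus holds no correlation between miRNAs and no difference between numbers within a set. For treated against control without the block, 6.6% of the changes of 1.5-fold, 35.2% of those of 2-fold and 83.9% of those of 4-fold were recovered. With the replicate block these shares were 47.5%, 76.9% and 97.1%, and 3.84% of calls were false. For 24 h against control they were 4.7%, 32.7% and 77.2% without the block and 7.3%, 40.6% and 83.5% with it. With no change simulated, 1 of 50 draws of the 24 h comparison without the block gave a call, and no draw of the other 3 fits did. A list of 8 members raised 2-fold had an unadjusted camera p under 0.05 in 100% of draws, and an unchanged list in 0% to 6%. Members were drawn without correlation, so correlated lists were not covered.

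Coordinates come from a match of the most frequent sequence to the miRNA hairpins of GENCODE 29 (GRCh38), since the table gives none, and are 1-based. Of the 296 tested miRNAs, 289 matched a hairpin of their own name and 10 of these also matched a hairpin of another name. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.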

Results

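Mature miRNAs were profiled in HK2 cells, a human renal proximal tubule epithelial line, with and without TGF-beta1. The series title concerns miR-17 and miR-20a in kidney fibrosis, and the stated design compares TGF-beta treated with control cells. There were 4 control libraries, 2 libraries after 24 h of TGF-beta and 2 after 48 h. Estimated depth was between 1440922 and 3091190 reads per library. Listed miRNAs took up 75.1% ± 4.93 (SD, n = 4) of reads in controls, 80.5% ± 8.25 (n = 2) at 24 h and 77.0% ± 2.63 (n = 2) at 48 h.

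The profile was dominated by miR-21-5p, a miRNA linked to fibrosis in many tissues, which matches chromosome 17, positions 59841273 to 59841294 (GRCh38, plus strand), within the transcribed region of VMP1. It made up 37.6% ± 2.09 (SD, n = 4) of all reads in controls, 50.9% ± 8.32 (n = 2) at 24 h and 42.2% ± 4.15 (n = 2) at 48 h. The next most abundant were let-7i-5p at 57069 ± 21266 CPM (SD, n = 4) in controls and miR-30a-5p, a kidney epithelial miRNA, at 26477 ± 4786 CPM. miR-26a-5p, miR-222-3p, let-7f-5p, miR-30c-5p, let-7a-5p, miR-30d-5p and miR-151a-3p completed the 10 most abundant. The miR-200 family, which keeps epithelial cells epithelial by targeting ZEB1 and ZEB2, was uneven in controls, with 7446 ± 936 CPM for miR-200b-3p, 43.5 ± 11.5 CPM for miR-200c-3p and 2.08 ± 2.10 CPM for miR-141-3p.

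Libraries differed mainly by the number in their titles. The first principal component of log2(CPM + 1) held 61.9% of the variance and put libraries 1 and 2 apart from libraries 3 and 4, among controls as among treated libraries. The second held 15.7% and put the 4 treated libraries apart from the 4 controls. In treated libraries the numbers coincide with exposure time, and in controls they do not mark any labelled difference. With treatment in the model, 138 of the 296 tested miRNAs differed between the number sets by limma at an adjusted p under 0.05, 101 of them higher in libraries 3 and 4.

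**Figure D1:**
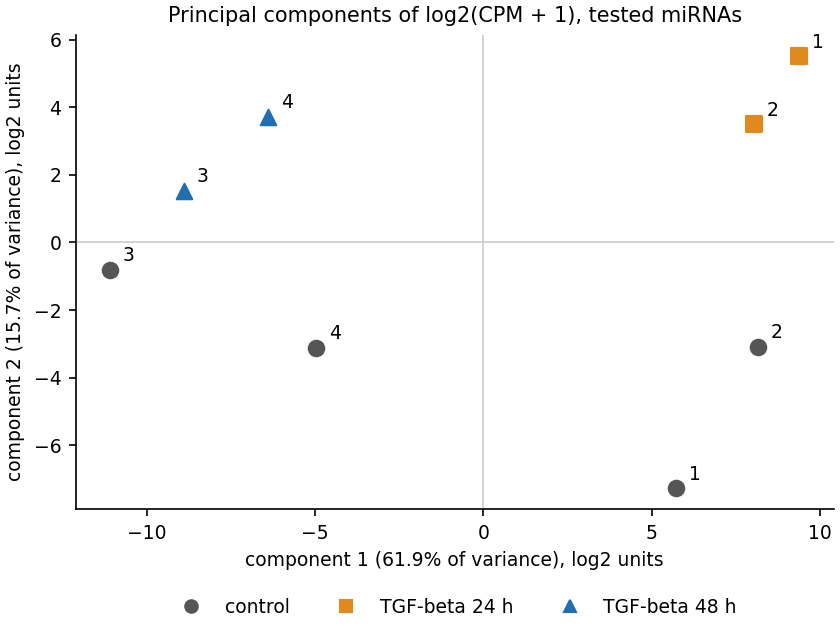
Scores of the 8 libraries on the first and second principal components of log2(CPM + 1) over 296 miRNAs, in log2 units, with the title number beside each point. Libraries 1 and 2 of every group lie to the right and libraries 3 and 4 to the left, and the 4 treated libraries lie above the 4 controls.

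The comparison of all treated with all control libraries asks which miRNAs TGF-beta changed in tubule cells. miR-584-5p was the miRNA that differed most clearly. It averaged 151 ± 35.6 CPM (SD, n = 4) in controls and 58.9 ± 14.9 CPM (n = 4) in treated libraries, a log2 fold change of -1.34 ± 0.29 (SE), and it was lower in 4 of 4 same-numbered pairs. Its sequence lies on chromosome 5, positions 149062374 to 149062394 (GRCh38, minus strand), in an intron of SH3TC2. Its adjusted p was 0.256 by limma without a block and 0.0158 with the replicate block. Without the block, limma called 0 of 296 miRNAs, with 31 at an unadjusted p under 0.05, and with the replicate block it called 1, miR-584-5p. With the block and median-of-ratios scaling it called 4, miR-584-5p (adjusted p = 0.0183), miR-143-3p and miR-379-5p (0.0248 each) and miR-7-5p (0.0305). This limits the single-miRNA results to changes that the spread between number sets does not hide.

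Among the miRNAs with the smallest p-values that did not pass without the block or with the replicate block on the deposited scaling, miR-381-3p was at 84.4 ± 24.7 CPM (SD, n = 4) in controls and 152 ± 6.72 CPM (n = 4) in treated libraries, with an adjusted p of 0.445 by limma and 0.0844 with the block. miR-379-5p was at 27.7 ± 4.74 CPM in controls and 49.9 ± 10.4 CPM in treated libraries, and miR-409-3p at 20.9 ± 2.67 and 32.9 ± 7.77 CPM. miR-181b-2-3p was at 13.3 ± 5.67 and 24.8 ± 4.64 CPM. Each of these, and miR-21-5p with a log2 fold change of 0.30 ± 0.12 (SE), was higher in 4 of 4 pairs. On the lower side, let-7d-3p was at 523 ± 179 CPM in controls and 255 ± 66.6 CPM in treated libraries, miR-197-3p at 69.2 ± 9.82 and 36.5 ± 12.2 CPM, and miR-149-5p at 166 ± 17.2 and 98.0 ± 13.0 CPM. These 3 were lower in 4 of 4 pairs. miR-222-3p, a miRNA of proliferating cells, was at 18929 ± 5189 and 11348 ± 1814 CPM and was lower in 3 of 4 pairs.

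**Figure D2:**
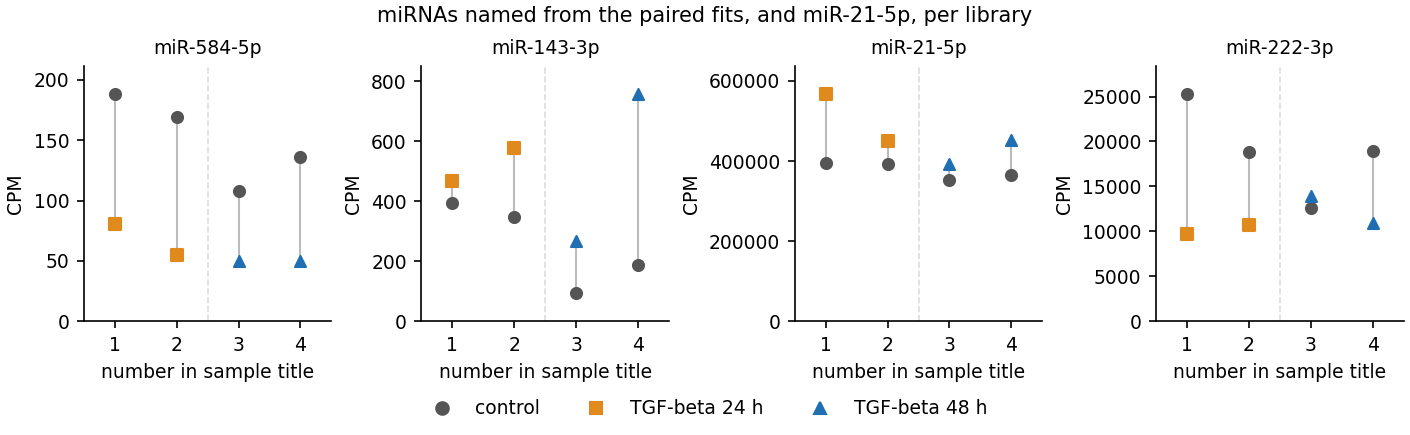
CPM of 4 miRNAs in each library against the number in the sample title, with same-numbered control and treated libraries joined by a line and the axes starting at 0. miR-584-5p was lower and miR-143-3p and miR-21-5p were higher in the treated library of every pair, while miR-222-3p was lower in 3 of the 4.

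As groups, the miRNAs of the 14q32 cluster stood highest. This imprinted cluster (DLK1-DIO3) encodes many miRNAs that are low in most adult epithelia, and 8 of the 41 in the table were abundant enough to test. Of these, miR-134-5p averaged 8.85 CPM in controls 1 and 2 and 7.75 CPM in controls 3 and 4, and miR-382-5p 8.25 and 7 CPM. Both reached the filter of 10 CPM only through the treated libraries, so the filter favoured a rise for them. All 8 had a positive log2 fold change, with a median of 0.61, which is 0.84 above the median of all miRNAs. They were miR-381-3p, miR-379-5p, miR-543, miR-411-5p, miR-409-3p, miR-654-3p, miR-134-5p and miR-382-5p, at positions 101022071 to 101065367 of chromosome 14 (GRCh38, plus strand) from the first to the last. Their list was higher than the other miRNAs by camera (adjusted p = 9.8e-08), and 2 of the 8 passed when adjusted over the list alone, against 0 over all miRNAs tested. The call is lost with an estimated correlation (adjusted p = 0.202) and with fry, which tests whether the members move one way and does not compare them with other miRNAs (adjusted p = 0.144). Summed over all 41 miRNAs of the list in the table, the cluster was at 278 ± 51.8 CPM (SD, n = 4) in controls, 358 ± 7.28 CPM (n = 2) at 24 h and 528 ± 57.9 CPM (n = 2) at 48 h.

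**Figure D3:**
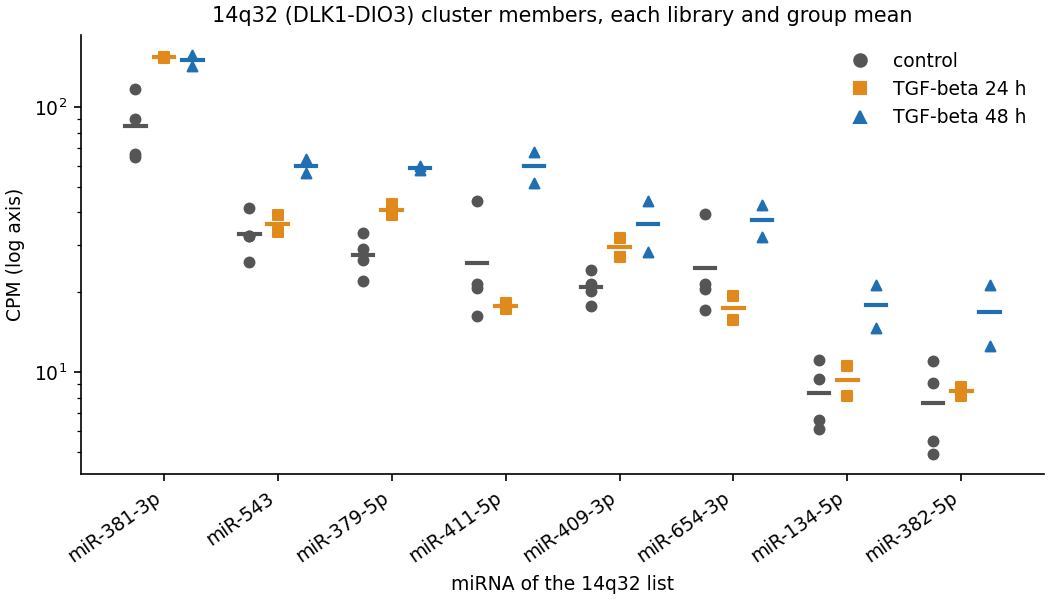
CPM on a log axis of the 8 tested miRNAs of the 14q32 list, with each library as a point and each group mean as a bar. Both 48 h libraries lie above all 4 controls for every member except miR-654-3p, whose highest control lies between them, while the 24 h libraries do so only for some members.

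The list of miRNAs reported to rise with TGF-beta or in kidney fibrosis was also higher than the other miRNAs (adjusted p = 0.00616 by camera). The call is lost with an estimated correlation (adjusted p = 0.202) and with fry (adjusted p = 0.607). Of its 10 tested members 9 lay above the median change, and the list median was 0.42 above it. miR-143-3p, a miRNA of smooth muscle and fibroblasts, was at 256 ± 141 CPM in controls and 518 ± 205 CPM in treated libraries and higher in 4 of 4 pairs, and miR-155-5p was at 7687 ± 763 and 7616 ± 3322 CPM. None of the 10 passed when adjusted over the list alone, and 1 did with the replicate block. 1 member, miR-382-5p, also belongs to the 14q32 list, and without it the adjusted p was 0.0292. The miR-30 family, abundant in kidney epithelium, was lower than the other miRNAs (adjusted p = 0.0299), with 10 of 11 members below the median change and a list median 0.21 below it, and the call is also lost with an estimated correlation (adjusted p = 0.202). None of its members passed when adjusted over the list alone without the block, and 4 did with it. miR-30a-5p was at 26477 ± 4786 CPM in controls and 20627 ± 3295 CPM in treated libraries, and miR-30c-5p at 12217 ± 2404 and 8481 ± 1970 CPM. The miR-30 call is also lost with median-of-ratios scaling (adjusted p = 0.0626), quantile normalization (0.0815) or CPM without the 10 most abundant miRNAs (0.0681), at a mean of at least 100 CPM (0.139), and without control library 2 (0.0796), control library 4 (0.106) or 48 h library 3 (0.22). In these settings the list median relative to all miRNAs stayed between -0.24 and -0.17.

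The miRNAs of the series title, miR-17-5p and miR-20a-5p, did not differ between treated and control libraries beyond the spread. They are encoded in an exon of MIR17HG on chromosome 13, miR-17-5p at positions 91350618 to 91350640 and miR-20a-5p at 91351072 to 91351094 (GRCh38, plus strand). miR-17-5p was at 600 ± 377 CPM (SD, n = 4) in controls and 483 ± 230 CPM (n = 4) in treated libraries, with a log2 fold change of -0.25 ± 0.48 (SE) and an adjusted p of 0.884 by limma. miR-20a-5p was at 1134 ± 901 and 786 ± 367 CPM, with -0.34 ± 0.53 and an adjusted p of 0.838. Each was lower in 2 of 4 pairs, and without control library 3 the log2 fold changes turn to 0.12 for miR-17-5p and 0.13 for miR-20a-5p. Without that library the controls lean to numbers 1 and 2, so unblocked values of this kind also hold a difference between number sets. Of the 9 tested members of the miR-17~92 cluster, 6 lay below the median change of all miRNAs and 3 above it, and none passed, while with the replicate block 1 passed when adjusted over the list alone. The cluster as a list did not differ from the other miRNAs (camera, adjusted p = 0.495), and its median relative to all miRNAs, -0.01, turns to 0.35 without control library 3 and is also above 0 without control library 4 (0.02), 24 h library 1 (0.09) or 24 h library 2 (0.01). Its most abundant member, miR-92a-3p, was at 5861 ± 2171 and 3364 ± 1033 CPM and lower in 4 of 4 pairs, with an adjusted p of 0.445 without the block and 0.0844 with it. Its sequence is also encoded on chromosome X, in the cluster of miR-106a and miR-363, so its reads cannot be assigned to one copy. miR-18a-5p, miR-18a-3p, miR-17-3p, miR-19a-3p, miR-19b-3p and miR-92a-1-5p had log2 fold changes between -0.72 and 0.08, and those of miR-18a-5p and miR-92a-1-5p change sign with median-of-ratios scaling. Signs also change without control library 3, to 0.33 for miR-19b-3p and 0.20 for miR-18a-5p, and without control library 2, to -0.38 for miR-19a-3p.

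The seed family, whose 6 tested members share the targeting sequence of miR-17, had 5 members below the median change and 1 above it, miR-106b-5p. None passed, and the list did not differ from the others (camera, adjusted p = 0.495). Its median relative to all miRNAs, -0.20, turns to 0.17 without control library 3. miR-93-5p had -0.52 ± 0.38 (SE), miR-106b-5p -0.19 ± 0.70, miR-20b-5p -0.62 ± 0.32 and miR-106a-5p -0.62 ± 0.46. The value of miR-106b-5p turns to 0.03 with quantile normalization and to 0.22 without control library 3. It is also above 0 without control library 4 (0.09), 24 h library 1 (0.20) or 24 h library 2 (0.13). Between the number sets 5 of the 6 differed, with treatment in the model, and were higher in libraries 3 and 4, while miR-20b-5p did not pass (adjusted p = 0.0987). miR-106b-5p averaged 147 CPM in controls 1 and 2 and 613 CPM in controls 3 and 4.

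**Figure D4:**
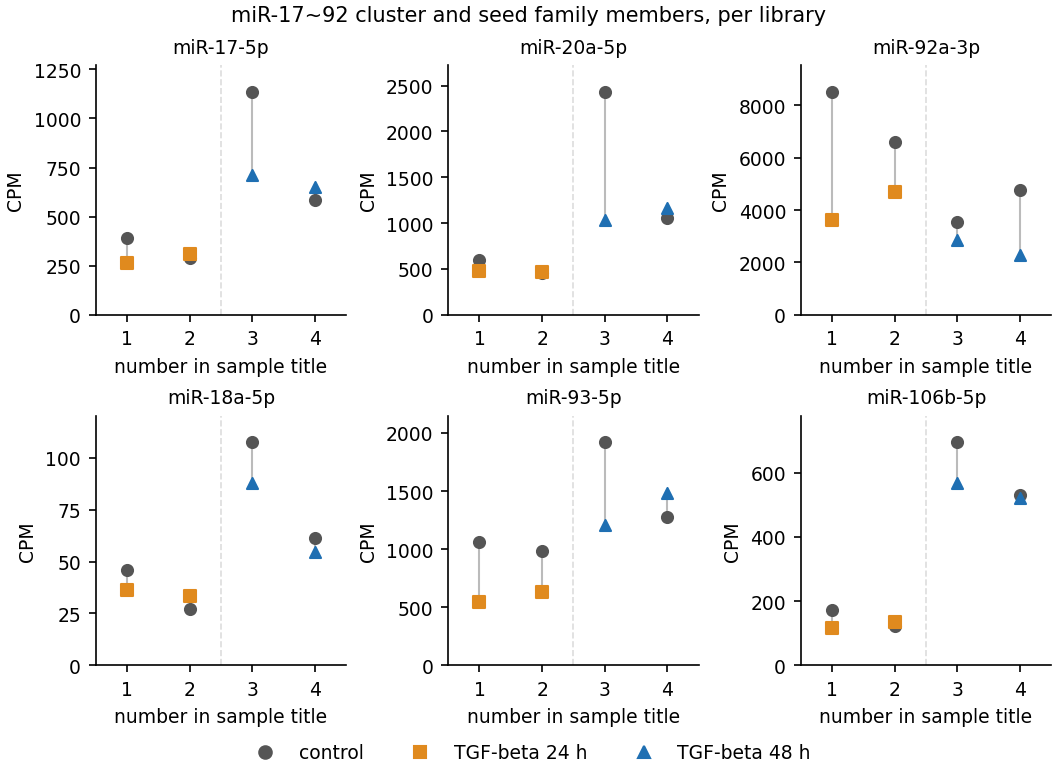
CPM of 6 miRNAs of the miR-17~92 cluster and its seed family in each library against the number in the sample title, with same-numbered control and treated libraries joined by a line. For miR-17-5p, miR-20a-5p and miR-106b-5p the gap between numbers 1 and 2 and numbers 3 and 4 is wider than the gap within most pairs, while miR-92a-3p was lower in the treated library of every pair.

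After 24 h of TGF-beta, the paired fit found lower levels of miR-584-5p and of miR-222-3p and miR-221-5p, from a cluster on chromosome X linked to proliferation. miR-221-3p of that cluster did not pass over all miRNAs, at 2090 and 2676 CPM in 24 h libraries 1 and 2 against 3996 and 3712 CPM in controls 1 and 2. miR-222-3p was at 10243 ± 720 CPM (SD, n = 2) against 18929 ± 5189 CPM (n = 4) in controls, with a log2 fold change of -1.09 ± 0.25 (SE, replicate block) and an adjusted p of 0.00267, and miR-221-5p at 98.6 ± 56.9 against 216 ± 35.7 CPM, with -1.41 ± 0.33. miR-584-5p was at 67.8 ± 18.6 against 151 ± 35.6 CPM, with -1.41 ± 0.34 and an adjusted p of 0.00292. miR-296-5p had a log2 fold change of -1.84 ± 0.42, from 12.6 ± 2.71 CPM in controls to 3.9 and 1.1 CPM in 24 h libraries 1 and 2. In these libraries 3 reads are 1.66 and 1.63 CPM. miR-197-3p was at 28.1 ± 10.1 against 69.2 ± 9.82 CPM. miR-92a-3p also passed, with -0.87 ± 0.28 and an adjusted p of 0.0394. In all, limma with the replicate block called 17 of 296 miRNAs, 2 higher (miR-590-3p and miR-548f-3p) and 15 lower, and without the block it called 0, with 72 at an unadjusted p under 0.05. The 2 higher ones were low in controls 1 and 2, miR-590-3p at 4.2 and 6.6 CPM and miR-548f-3p at 3.5 and 8.8 CPM. With the replicate block and median-of-ratios scaling the count was 0, and with the block of 2 number sets it was 0. Without the block but with only controls 1 and 2 the count was 52, and without control library 2 it was 18. Leaving out control library 2 makes the controls lean to numbers 3 and 4, so the count of 18 mixes exposure with the number sets.

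Of the lists, the 14q32 cluster was higher than the other miRNAs at 24 h (camera, adjusted p = 0.0032), with 7 of 8 members above the median change and a median of 0.59 above it. With an estimated correlation its adjusted p = 0.41, and with fry 0.165. The list of miR-221 and miR-222 was lower with the replicate block (adjusted p = 0.00678) but not without it (adjusted p = 0.0969), and with the block and an estimated correlation its adjusted p = 0.859. Without the block it passed without control library 3 (0.0295) or 24 h library 2 (0.0172), at a mean of at least 1 CPM (0.0287), with no filter (0.00991) and with fry (0.0113). All 3 tested members passed when adjusted over the list alone in both fits. The miR-17 seed family had a median 0.62 below that of all miRNAs without the block and 0.09 above it with the block, and passed in neither (adjusted p = 0.231 and 0.854), although the unblocked test called it at a mean of at least 1 CPM (adjusted p = 0.0399) and without a filter on low values (0.00991). For the miR-17~92 cluster the medians were 0.46 below and 0.21 above, and it passed in neither (adjusted p = 0.42 and 0.854), although without a filter the unblocked test called it (0.0235). The unblocked values compare 24 h libraries numbered 1 and 2 with controls of all 4 numbers. miR-425-3p, named as one of the 3 smallest unblocked p-values, was at 8.50 ± 0.28 against 25.8 ± 9.54 CPM and passed in neither fit. It averaged 17.75 CPM in controls 1 and 2 and 33.85 CPM in controls 3 and 4.

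After 48 h, miR-143-3p showed the clearest rise within pairs, to 514 ± 347 CPM (SD, n = 2) against 256 ± 141 CPM (n = 4) in all controls, with a log2 fold change of 1.76 ± 0.33 (SE, replicate block) and an adjusted p of 2.54e-05. This fold change uses controls 3 and 4 only, at 93.2 and 188 CPM. Controls 1 and 2, at 396 and 348 CPM, lay above 48 h library 3, at 269 CPM. The sequence of miR-143-3p lies on chromosome 5, positions 149428978 to 149428998 (GRCh38, plus strand), within CARMN, a long non-coding RNA gene. miR-145-5p, which is encoded beside it, stayed between 0 and 2.7 CPM in all 8 libraries. With the replicate block miR-7-5p had a log2 fold change of 1.05 ± 0.27 and miR-98-5p, a let-7 family member, one of 1.01 ± 0.29 (adjusted p = 0.00889 and 0.0223), and both calls are lost with median-of-ratios scaling beside the block (0.105 and 0.155). miR-98-5p went from 856 to 3156 CPM in number 3 and from 1938 to 2121 CPM in number 4. Without the block the value of miR-7-5p was 0.30, and without control library 3 it was -0.07. Those that fell included miR-6747-3p, from 14.5 ± 2.76 to 4.00 ± 0.85 CPM, miR-130b-5p, by -1.34 ± 0.33 in log2 from 254 ± 64.6 CPM, and miR-615-3p, from 458 ± 163 to 149 ± 31.0 CPM. let-7d-3p had -1.24 ± 0.32 and miR-584-5p -1.27 ± 0.34, with adjusted p-values of 0.00889 and 0.00922. The pairs of let-7d-3p differed, from 367 to 248 CPM in number 3 and from 646 to 169 CPM in number 4. The SE and p-values of this fit rest on the spread over all tested miRNAs, so they do not show that the pairs agree. limma with the replicate block called 11 of 296 miRNAs, 4 higher and 7 lower, and without the block 0, with 50 at an unadjusted p under 0.05. With the replicate block and median-of-ratios scaling 4 were called, miR-143-3p, miR-584-5p, miR-130b-5p and miR-615-3p, with the block of 2 number sets 0, and without the block but also without control library 3, 39. Leaving out control library 3 makes the controls lean to numbers 1 and 2. That count and the -0.07 of miR-7-5p therefore mix exposure with the number sets.

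The 14q32 list was again higher than the other miRNAs (camera, adjusted p = 4.73e-05), with 8 of 8 members above the median change, a median of 0.87 above it, and 7 of 8 members past the threshold when adjusted over the list alone. The fibrosis list (adjusted p = 0.0181) was higher, with 9 of 10 members above the median change, and the miR-30 family (adjusted p = 0.0185) was lower, with 9 of 11 below it. These 3 calls held with the replicate block and were lost with an estimated correlation (adjusted p = 0.184, 0.189 and 0.202). Without control library 4 the fibrosis and miR-30 calls are lost (adjusted p = 0.0537 and 0.0564), as they are without 48 h library 4 for the fibrosis list (0.0616) and without 48 h library 3 for the miR-30 family (0.127), and both are lost at a mean of at least 100 CPM (0.0563 each). The miR-23a27a24-2 cluster, reported as responsive to TGF-beta, was higher without the block (adjusted p = 0.0229) but not with it (adjusted p = 0.0812). With an estimated correlation its adjusted p = 0.386, and with fry 0.101. That call is also lost without control library 4 (0.0537), without 48 h library 4 (0.0758) and at a mean of at least 100 CPM (0.0563). Its member miR-27a-3p averaged 2467 CPM in controls 1 and 2, 9272 CPM in controls 3 and 4 and 9477 ± 2155 CPM (n = 2) at 48 h. The let-7 family was higher with the block (adjusted p = 0.0176) but not without it (adjusted p = 0.868), and with the block and an estimated correlation its adjusted p = 0.657. With the block and median-of-ratios scaling it was not called (adjusted p = 0.06). Its rise with the block lay mostly in number 3, where let-7a-5p went from 4992 to 12635 CPM. In number 4 most members fell, let-7a-5p from 11131 to 6968 CPM. The miR-17 seed family had a median 0.10 above that of all miRNAs without the block and 0.35 below it with the block (adjusted p = 0.85 and 0.087), and the miR-17~92 cluster one 0.19 above and 0.43 below (adjusted p = 0.868 and 0.0726).

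The direct comparison of 48 h with 24 h tests whether the exposure times differed. limma called 0 of 296 miRNAs without the block, with 82 at an unadjusted p under 0.05, and 0 with the replicate block, with 45. Without the block, miR-31-5p had 68.3 ± 6.93 CPM (SD, n = 2) at 24 h and 265 ± 12.9 CPM (n = 2) at 48 h, with an adjusted p of 0.058. As exposure time coincides with the title numbers, only the fit with the block sets each time against the controls that share its numbers. In that fit the change of the let-7 family from these controls was higher at 48 h than at 24 h, relative to the other miRNAs (camera, adjusted p = 0.00197). The difference was above 0 for 9 of 9 members, with a median 0.58 above that of all, whereas without the block the median lay 0.22 below. The summed CPM of the family was 98452 ± 2449 (SD, n = 2) at 24 h and 89545 ± 13816 (n = 2) at 48 h, so its summed level was not higher at 48 h. The blocked call is lost with an estimated correlation (adjusted p = 0.858) and with median-of-ratios scaling beside the block (adjusted p = 0.0747). Without the block camera called 0 lists, with 0 at an unadjusted p under 0.05, although without a filter on low values it called 4, with the miR-17 seed family among them (adjusted p = 0.0333). By contrast fry, which does not compare a list with other miRNAs, called 7. Without control library 3 the single-miRNA count without the block was 85, and without control library 2 it was 41.

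Across the 296 miRNAs, the log2 fold changes at 24 h and at 48 h against all 4 controls had a correlation of -0.10 and a covariance of -0.03. Simulated groups with no effect, which share the same controls, gave 0.33 and 0.07. Against all 4 controls, a difference between number sets moves the 24 h and 48 h values in opposite directions. The gap from the simulated values therefore decides nothing about TGF-beta. With the controls crossed, so that each time was set against controls of the other numbers, the correlation was -0.64. With each time set against its own-numbered controls, so that no control was shared, the correlation was 0.35, Spearman's rho was 0.31, the covariance was 0.08, and 58.4% of miRNAs changed in the same direction. These are correlations across genes, which are not independent replicates. Only miR-584-5p was called at both times with the replicate block, against 0.35 expected for independent lists of falling miRNAs.

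Of the lists not yet described, none passed by camera in any comparison without the block at the filter of 10 CPM. By fry the miR-106b~25 cluster passed in treated against control (adjusted p = 0.0148) and at 24 h (0.0113), the cluster of miR-183, miR-96 and miR-182 at 24 h (0.00147) and at 48 h against 24 h (0.00386), and the miR-15/16 and miR-200 families at 48 h against 24 h (0.0423 and 0.0477). In treated against control, the adjusted p was 0.124 for the miR-106b~25 cluster, where 0 of 6 members were higher, and 0.179 for the cluster of miR-106a and miR-363, where 0 of 3 were. Without a filter on low values both passed (adjusted p = 0.027 for each). It was 0.113 for the miR-23a27a24-2 cluster and also for the cluster of miR-221 and miR-222. The first of these passed without 24 h library 1 (adjusted p = 0.0411) and the other without a filter on low values (0.0272). The adjusted p was 0.481 for the let-7 family, 0.808 for the miR-200 family and the miR-15/16 family, 0.737 for the miR-29 family, which targets collagen mRNAs, and 0.495 for the cluster of miR-183, miR-96 and miR-182. miR-200b-3p was at 7446 ± 936 CPM (SD, n = 4) in controls, 5899 ± 758 CPM (n = 2) at 24 h and 8071 ± 1749 CPM (n = 2) at 48 h. miR-29a-3p was at 1784 ± 629, 936 ± 51.5 and 2113 ± 742 CPM. It averaged 1348.5 CPM in controls 1 and 2 and 2219 CPM in controls 3 and 4, so these group means mix exposure with the number sets.

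Lists with fewer than 3 tested members were not tested as lists, and no member of them passed in treated against control without the block or with the replicate block on the deposited scaling. The tubule miRNA miR-192-5p was at 737 ± 109 CPM (SD, n = 4) in controls and 513 ± 97.5 CPM (n = 4) in treated libraries, and miR-204-5p was listed at 0 in all 8 libraries. miR-34a-5p, a target of p53, was at 22.8 ± 13.0 CPM in controls, 5.50 ± 0.71 CPM (n = 2) at 24 h and 26.0 ± 5.66 CPM (n = 2) at 48 h, and miR-210-3p, a marker of hypoxia, at 596 ± 137, 366 ± 67.5 and 543 ± 37.2 CPM. These means mix exposure with the number sets. miR-34a-5p averaged 12.05 CPM in controls 1 and 2 and 33.6 CPM in controls 3 and 4, and miR-210-3p 487 and 705 CPM. Of the markers of other cells, the blood miRNA miR-451a was at or below 0.8 CPM in all libraries, while miR-142-3p was at 167 ± 108 CPM in controls and 159 ± 50.2 CPM in treated libraries. The endothelial miR-126-3p was at 640 ± 74.5, 470 ± 87.5 and 720 ± 247 CPM. Of the fibroblast and smooth muscle markers only miR-143-3p was abundant enough to test, and it passed in treated against control with the replicate block and median-of-ratios scaling (adjusted p = 0.0248). The list of liver, muscle and neuron miRNAs did not pass (adjusted p = 0.124), and its most abundant member, miR-9-5p, was at 778 ± 130 CPM in controls and 848 ± 78.6 and 763 ± 46.8 CPM after 24 and 48 h. Entries that overlap other small RNAs did not differ between treated and control libraries (adjusted p = 0.495). With the replicate block their change from same-numbered controls was higher at 48 h than at 24 h (adjusted p = 0.0472, and 0.858 with an estimated correlation). With median-of-ratios scaling beside the block that call is lost (adjusted p = 0.0747). In this list miR-1246 was at 310 ± 59.1 CPM in controls, 258 ± 36.1 CPM at 24 h and 556 ± 357 CPM at 48 h.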

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

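The tests of exposure time, of the reads taken up by miR-21-5p, of the number of miRNAs called in other splits of the libraries and of the 14q32 list among the splits that part all 4 pairs were chosen only after the result was seen, as was the block of 2 number sets.

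Of 80 results checked for a library far from the others of its group, 1 stood out, which is fewer than the 1 in 20 that chance gives. In controls, miR-17-3p was highest in library 3, with a gap to the next library of 0.861 of the range of the group. With the replicate block, the change of the let-7 family from same-numbered controls was higher at 48 h than at 24 h (camera, adjusted p = 0.00197). The same held for the entries that overlap other small RNAs (adjusted p = 0.0472), and both calls are lost with an estimated correlation (adjusted p = 0.858 for each).

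Libraries 1 and 2 lay apart from libraries 3 and 4 in every group, with 138 of 296 miRNAs past the threshold between these sets. After a trend per library was removed, 112% as many miRNAs were past the threshold for GC content, 125% for uridine content, through which 4-thiouridine would act, and 123% for length, with 113, 123 and 122 of the 138 among them, which argues against each as the whole cause. The difference in unexposed controls correlated across miRNAs with that in treated libraries at 0.811, which argues against TGF-beta exposure time. Among miRNAs of at least 100 CPM, the median difference between the control sets was 30.1 times that of Poisson counting, but libraries 1 and 2 had 1440922 to 2270148 estimated reads and libraries 3 and 4 had 2403846 to 3091190, so a bias that follows depth cannot be told apart from the number sets. A difference in harvest time, culture or library batch stays open and untested, since the labels name none, and in treated libraries the number sets cannot be told apart from the exposure times.

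The median miRNA was lower at 24 h than in controls by 0.41 on the log2 scale (-0.41). Against all 4 controls, the higher CPM of miR-21-5p alone would shift all other reads by -0.35, so the reads taken up by this miRNA may account for most of that value. With the replicate block the observed median was -0.45. miR-21-5p was at 39.6% and 39.2% of reads in controls 1 and 2, above the 37.6% mean of all controls. Against these 2 controls the shift would be smaller and account for less, and it was not computed. This shift rests unevenly on the 24 h libraries, with miR-21-5p at 56.8% of reads in library 1 and 45.1% in library 2. At 48 h the same shift would be -0.11. The observed median was 0.07 without a block, where the explanation was not borne out, and -0.05 with the replicate block. The 48 h value therefore decides nothing. The shift at 24 h argues for reading changes at that time relative to the median, and no biological explanation of it was tested.

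The 14q32 list was higher in treated libraries, a call that is lost with an estimated correlation (adjusted p = 0.202, and 0.448 with the replicate block). With median-of-ratios scaling its median log2 fold change was 0.76, and 107% of its median relative to all miRNAs stayed after a GC trend was removed, which argues against CPM scaling and GC content. Its median lay at percentile 99.97 of 10000 lists matched on abundance. The real grouping gave the smallest p of the 35 splits of the libraries into 4 and 4 (6.12e-09, against 1.27e-07 for the next), so 1 of 35 splits did as well. Only 8 of the splits part all 4 same-numbered pairs, as the real one and the next do, and 8 are too few for a share under 0.05. A rise with TGF-beta exposure is a hypothesis, with culture or harvest differences between control and treated libraries untested.

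The real count of miRNAs past the threshold in treated against control was 0, so all 35 of 35 splits reach it by construction and the comparison decides nothing. The highest, 119, came from the split by number set, which points to that structure of the libraries. For the number of lists, 8 of 35 splits gave at least the real count of 3, and the highest other gave 5, so chance cannot be excluded. With the replicate block the real count was 1 miRNA and the highest of the others 0, and the 8 splits, of which 1 gave as many, are too few for a share under 0.05.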

How the results depend on the processing

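The number-set block, the replicate block with median-of-ratios scaling, and the alternatives for the list tests other than median-of-ratios scaling, the replicate block, an estimated correlation and fry were chosen after seeing the data. Tests for counts were planned for recovered whole reads and were not run, since reads were not recovered. At a mean of at least 100 CPM the 14q32 list had too few members to test. Depth limits low miRNAs, since 3 reads are up to 2.08 CPM. Where an alternative changed a value, the cause was not tested. Leaving out 1 control makes the controls uneven over the number sets. Unblocked comparisons with controls then mix exposure with the difference between these sets. In fits that leave 1 library in a group, that library is assumed to vary like the other groups.

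For single miRNAs the count was 0 in all 4 comparisons. For treated against control it was 1 with the replicate block, 1 with the number-set block and 4 with the replicate block and median-of-ratios scaling, and 0 without any 1 library. At 24 h it was 17 with the replicate block, 52 with controls 1 and 2 only, and from 0 to 18 without 1 library (18 without control 2). At 48 h it was 11 with the replicate block, 4 with the block and median-of-ratios scaling, and from 0 to 39 without 1 library (39 without control 3). At 48 h against 24 h it was from 0 to 85 without 1 library (85 without control 3, 41 without control 2).

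For lists the counts were 3 for treated against control, 1 at 24 h, 4 at 48 h and 0 for 48 h against 24 h. For treated against control it was 7 with no filter on low values, 1 at a mean of at least 100 CPM, 0 with an estimated correlation and 0 with that and the replicate block. At 24 h it was 3 at a mean of at least 1 CPM, 8 with no filter, 0 at 100 CPM, 2 with the replicate block, 2 with controls 1 and 2 only, 2 with the number-set block, 2 with the replicate block and median-of-ratios scaling, 0 with an estimated correlation, 0 with that and the replicate block, 4 with fry, and from 1 to 2 without 1 library. At 48 h it was 0 at 100 CPM, 0 with an estimated correlation, 0 with that and the replicate block, and from 1 to 4 without 1 library (1 without control 4, 2 without 48 h library 4). At 48 h against 24 h it was 4 with no filter, 2 with the replicate block, 1 with the number-set block and 7 with fry. The let-7 family reversed in that comparison, to a higher change at 48 h from controls of the same numbers, with the replicate block (adjusted p = 0.00197) and the number-set block (adjusted p = 0.0194). This call is lost with an estimated correlation beside the replicate block (0.858) and with median-of-ratios scaling beside it (0.0747).

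Of the values of named miRNAs under alternatives, 1717 kept their sign and side of the threshold, 102 changed sign without passing in either, and 49 moved past the threshold. Of those of single lists, 1299 kept the sign of the median and the side, 149 changed that sign and kept the side, 38 moved past the threshold (4 with a change of sign), 40 fell short of it and 2 reversed. With fry the 14q32 and fibrosis calls in treated against control (adjusted p = 0.144 and 0.607) and the 14q32 call at 24 h (0.165) are lost.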

Other observations

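Among controls, miR-574-5p, which matches an intron of FAM114A1, averaged 797 CPM in libraries 1 and 2 and 51.2 CPM in libraries 3 and 4, a log2 difference of -4.36 with treatment in the model. miR-708-5p, in an intron of TENM4, averaged 20.6 and 241 CPM, with a difference of 3.77. miR-23a-3p and miR-27a-3p, which share a cluster, were higher in libraries 3 and 4 by 2.32 and 1.96 on the log2 scale.

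In control library 1, the most frequent sequence had no added, mismatched or missing base for 208 of the 296 tested miRNAs, which includes reads shorter than the annotated sequence. It carried bases added at the 3′ end for 70 and at the 5′ end for 8, a mismatch for 9 and a missing base for 12. For 8 tested miRNAs it was shared with another tested miRNA. miR-145-3p, encoded beside miR-143-3p, was between 0 and 2.2 CPM in controls and between 1.9 and 5.4 CPM in treated libraries.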
